A study of Macaca mulatta with 12 samples.

How the data were processed

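RNA was measured in 12 libraries of macrophages that carry CD14 and CD163 but not CD16, sorted from the blood of rhesus macaques (Macaca mulatta). The animals had received back their own CD34+ blood-forming cells after CRISPR/Cas9 treatment, and the study's title names TET2-mutant clonal hematopoiesis. Sorting took place 4.5 months (early) or 19 months (late) after transplant. Wells of 250000 cells were then kept for 8 h either unstimulated (CTL) or with lipopolysaccharide (LPS) at 100 ng/ml together with interferon-gamma at 20 ng/ml (ACT), per the labels. The treatment field of the labels names LPS alone, while the protocol names both. Each of the 4 groups has 3 libraries. No label says whether replicates are separate animals or separate wells, so the p-values measure only the spread between these libraries, which may be technical. No label gives a library or sequencing date.

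Total RNA was made into cDNA with SMART-Seq v4, which does not mark the strand, and into libraries with Nextera XT, per the labels. The deposited gene table holds a raw count per gene and library, whole numbers with no scaling. Its build is Mmul_8.0.1 and bcl2fastq is named, while the aligner and the counting tool are not given in the sources used here. A pair of tables deposited by the authors compares late with early libraries, for unstimulated and for stimulated cells. In those tables the authors list a log2 fold change of late over early, its standard error and a mean normalized count. The test score in the authors' tables is the log2 fold change over its standard error. Every p-value in the authors' tables comes with an adjusted value, and only genes with an adjusted p under 0.05 are listed. Their column names resemble those of a DESeq2 results table, though those of the p-values differ, and the tool is not stated.

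The count table has 32386 genes, 29857 under Ensembl identifiers and 2529 under symbols. A name table gave symbols to 15138 identifiers, a further 448 were named only in the authors' tables, and 12 were named from a description. For 137 identifiers the sources gave differing names, and 2326 symbols found more than once were left as identifiers. In all 15789 genes had a name, and genes without one held 11.6% of the counts. The main list tests did not use names found only in the authors' tables, such as that of IL1B. A larger share of the counts therefore lay outside the reach of the lists. Among the genes without a usable name were CXCL8, ISG15 and the guanylate-binding genes GBP1, GBP2, GBP4 and GBP5. No column of the count table was left out, and 6017 genes had a count of 0 in every library. Library totals ran from 3910680 to 12972505 counts. Reads carry no molecular identifiers, so intervals cover counting error only.

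Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, robust) in R 4.3.3, with TMM scaling, the filterByExpr filter by group and a coefficient per group over all 12 libraries. This left 11826 genes. The 5 contrasts were late against early in unstimulated and in stimulated cells, stimulated against unstimulated at each time, and the difference between the early and late stimulation responses (interaction). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error is the absolute log2 fold change over the square root of F. CPM values are each gene's counts scaled to a common library total, without TMM factors. The factors ran from 0.879 to 1.10 and were lowest in early stimulated libraries, so a fold from the test can differ from a ratio of mean CPM. The biological coefficient of variation was 0.143.

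Gene lists, 20 of pathways and 10 of cell type markers, were tested with camera in limma 3.58.1 with a preset correlation of 0.01, on log2 CPM with a prior count of 2. At least 5 tested members were required, which 26 lists had. P-values of lists were adjusted over the lists within a comparison. The lists, the tests, the rule for named genes and most of the alternatives were chosen before the data were examined. By that rule the text names up to 8 genes per direction and comparison with the largest log2 fold change. These had to pass the threshold, have a symbol, reach a mean CPM of 5 in a compared group and, except for the interaction, have no overlap between the groups' libraries. It also names up to 4 members of each described list with the smallest p, TET2 in every comparison, TET1, TET3, DNMT3A and ASXL1 once, and IL1B, IL6, TNF, CXCL8, NLRP3, CD14 and CD163 where tested. TET1 was too low to be tested.

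The pipeline was tested on simulated data with 200 changed genes of 11826 in each comparison. The changed genes were drawn from those with a mean CPM over 1, and no library was made to stand apart from its group. The recovery rates therefore do not cover genes under 1 CPM. At a 4-fold change it recovered 92% of the changed genes for late against early in unstimulated cells and 91% in stimulated cells. The same figure was 92% for early stimulation, 87% for late stimulation and 82% for the interaction. At a 2-fold change recovery was 65%, 67%, 55%, 65% and 38% in the same order, with 7 to 12 false calls per comparison.

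Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, other low-count filters, the replicate number as a block, only the compared groups, stricter thresholds, each library left out in turn, and for lists an estimated correlation or fry. The filter at a mean CPM of 5 and the list members named in the authors' tables were added after the data were seen. Data were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and with version 1.17.8 of data.table, and plots were drawn with matplotlib 3.10.9. Editing at TET2 and the size of mutant clones were not analysed here, since counts per gene do not show edits.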

Results

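Gene expression was measured by RNA-seq in sorted blood macrophages of rhesus macaques, taken 4.5 or 19 months after transplant of autologous, CRISPR/Cas9-treated CD34+ cells. Cells were left unstimulated or were stimulated for 8 h with LPS and interferon-gamma, which drive inflammatory activation of macrophages. The design asks how expression differs between the times and how the response to stimulation differs between them. There were 3 libraries in each of the 4 groups. Total counts were 6245345, 9843650 and 10905354 in early unstimulated, 4602109, 12972505 and 12934170 in early stimulated, 3910680, 7350214 and 6483122 in late unstimulated, and 7756530, 7653575 and 9270554 in late stimulated libraries.

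Late libraries held counts in more genes than early ones at the same depth. With every library thinned to 3910680 counts, early libraries had a count in 13637 to 13955 genes and late libraries in 17470 to 18717. Genes with a mean CPM under 1, 15151 in number, summed to 1521 ± 53.2 CPM (SD, n = 3) in early unstimulated and 4847 ± 525 CPM in late unstimulated libraries. The sums in stimulated libraries were 1377 ± 49 CPM early and 4872 ± 171 CPM late. Mitochondrial genes listed by symbol summed to 3753 to 4504 CPM in early and 5128 to 6257 CPM in late libraries. The first principal component held 56% of the variance and parted early from late libraries. Library Early ACT 1 stood apart from its group on the second component (11% of the variance, -61.46 against 1.49 and 1.79).

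**Figure D1:**
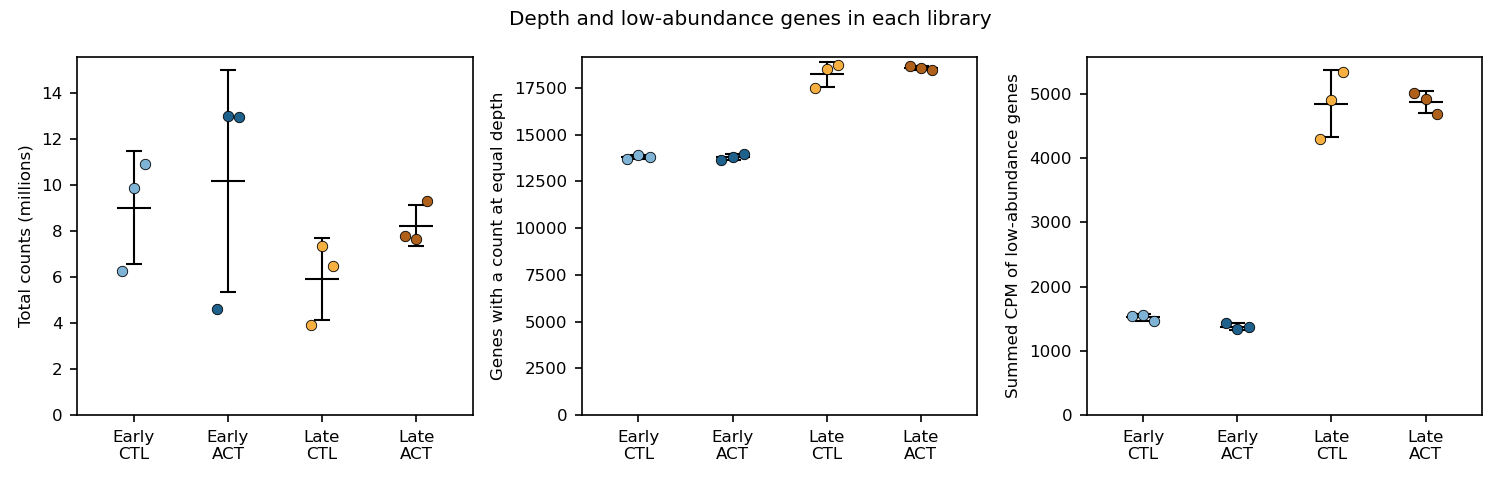
Total counts, genes with a count at equal depth and the summed CPM of genes with a mean CPM under 1, with a point for each of the 12 libraries by group. The 6 late libraries lie above the 6 early ones in the number of genes (17470 or more against 13955 or fewer) and in the summed CPM of low-abundance genes.

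TET2, whose product oxidizes methylated cytosine in DNA and which is often mutated in clonal hematopoiesis, was expressed in all 12 libraries. Its level was 270.5 ± 9.37 CPM in early unstimulated, 289.5 ± 34 in early stimulated, 419.8 ± 6.53 in late unstimulated and 424.9 ± 10.4 CPM in late stimulated libraries (SD, n = 3 each). The late level was higher by a log2 fold change of 0.73 ± 0.11 (SE) in unstimulated cells (adjusted p = 8.78e-06) and 0.40 ± 0.11 in stimulated cells (adjusted p = 0.0044, edgeR quasi-likelihood test, Benjamini-Hochberg). The authors' deposited table gives 0.74 ± 0.07 (adjusted p = 1.04e-21) and 0.41 ± 0.13 (adjusted p = 0.0128) for TET2 in the same comparisons. The rise on early stimulation, 0.38 ± 0.11 (adjusted p = 0.0306, edgeR quasi-likelihood test), was lost in 8 alternatives, with adjusted p from 0.0544 to 0.139. These were the replicate block, no low-count filter, only the compared groups, and leaving out Early CTL 1, 2 or 3 or Early ACT 2 or 3. TET2 did not pass on late stimulation (0.05 ± 0.11, adjusted p = 0.9985) or in the interaction (-0.33 ± 0.15, adjusted p = 0.433). The count table lists TET2 by its symbol, and the authors' deposited table places it, as ENSMMUG00000017831, on chromosome 5 of build Mmul_8.0.1 from 105087660 to 105219996.

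Unstimulated macrophages at 19 months expressed inflammatory cytokine genes at higher and interferon-stimulated genes at lower levels than at 4.5 months. IL1B, which encodes the inflammatory cytokine interleukin 1 beta, rose 3.16-fold, from 14050 ± 605 to 41580 ± 4882 CPM (SD, n = 3 each). TNF rose 3.0-fold, from 425 ± 8.43 to 1197 ± 128 CPM, and IL6 2.59-fold, from 34.1 ± 2.88 to 82.4 ± 2.86 CPM. The antiviral gene MX1 was 2.99-fold lower late (268.7 ± 6.09 against 83.9 ± 5.26 CPM), and OAS2, a sensor of double-stranded RNA, 4.66-fold lower (156 ± 1.98 against 31.5 ± 3.23 CPM). S100A9, a calcium-binding alarmin of monocytes, was 5.77-fold lower, at 113 ± 22.4 CPM late and 700.3 ± 26.7 CPM early. On build Mmul_8.0.1 the authors' deposited table places IL1B (ENSMMUG00000042751) on chromosome 13 from 107818918 to 107828254, TNF (ENSMMUG00000045654) on chromosome 4 from 32435035 to 32436829 and IL6 (ENSMMUG00000019983) on chromosome 3 from 85553880 to 85559671. In the authors' deposited table MX1 (ENSMMUG00000015329) lies on chromosome 3 from 5221826 to 5251031, OAS2 (ENSMMUG00000008505) on chromosome 11 from 113012695 to 113045940 and S100A9 (ENSMMUG00000006868) on chromosome 1 from 127955297 to 127958533.

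In all 4813 genes passed the edgeR quasi-likelihood test at 0.05 after Benjamini-Hochberg adjustment, 2471 higher and 2342 lower late. Among tested genes with a mean CPM under 1, 411 of 630 were higher and 6 lower, whereas above 100 CPM 380 were higher and 494 lower. The filter by group kept 630 of 15151 such low-abundance genes and favours those concentrated in some groups, so their share called is not that of all of them. The share higher was 51.3%, against 55.2% with RLE factors and 63.3% with upper-quartile factors, which shifted the median of all genes from 0.02 to 0.15. DESeq2, which also tested other genes (17678), gave 64.4%. The authors' deposited table for this comparison lists 5229 genes, 3144 of them higher. As no label gives a date, time and any batch that went with it cannot be told apart.

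Inflammatory cytokines and chemokines rose in all 15 tested members (15 adjusted over the list alone). Their median log2 fold change was 1.62 (camera adjusted p = 1.34e-13, and adjusted p = 0.000718 with an estimated correlation). IL1B (1.66 ± 0.11 SE, adjusted p = 2.24e-11, edgeR quasi-likelihood test), CCL3 and CXCL2 are named only by a symbol or description in the authors' deposited table and are not among these 15. Of the tested members, CXCL1, which attracts neutrophils, rose by 1.99, CCL2, which attracts monocytes, by 2.36, CCL20 by 1.62 and CSF3, the granulocyte growth factor, by 1.74. CXCL1 belongs to a family of close paralogs whose reads can be shared. NLRP3, the inflammasome sensor that leads to release of mature interleukin 1 beta, rose by 0.46 ± 0.11 (adjusted p = 0.00135, edgeR quasi-likelihood test).

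Type I interferon-stimulated genes fell in 22 of 28 tested members (22 adjusted over the list alone) with none higher, and their median was -1.08 (camera adjusted p = 8.64e-11). Examples are OAS2 at -2.22, MX1 at -1.58 and IFIT5 at -1.94. Genes of the interferon-gamma response fell in 14 of 19 (16 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 1.59e-05). With an estimated correlation the camera adjusted p was 0.000718 for the interferon-stimulated list and 0.00727 for the interferon-gamma list. PSMB8 (-1.47) and PSMB9 (-1.56), subunits of the immunoproteasome, TAPBP (-1.11), which loads peptides on MHC class I, and the chemokine gene CXCL10 (29.9 ± 4.27 to 4.73 ± 2.01 CPM, 6.17-fold) were lower.

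Markers of CD14 monocytes fell in 8 of 9 tested members, with 1 higher (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 7.31e-05, and adjusted p = 0.0186 with an estimated correlation). S100A8, the partner of S100A9, was at -2.25 and the matrix proteoglycan VCAN at -1.06. Marker sums of neutrophils (181.6 ± 11.8 and 105.8 ± 16.7 CPM early and late) and of CD16 monocytes (210.3 ± 4.42 and 149 ± 9.46 CPM) were also lower in every late library, though their lists did not pass (camera adjusted p = 0.593 and 0.733). CD163, the hemoglobin scavenger receptor used in the sort, was 2.04-fold lower (1301 ± 38.9 to 597 ± 17.2 CPM) and CD14, the LPS co-receptor, 1.44-fold lower (2359 ± 79.1 to 1534 ± 191 CPM).

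Metabolic and lysosomal genes leaned lower, with list calls that were lost with an estimated correlation. Glycolysis and hypoxia genes were lower in 12 and higher in 3 of 25 (14 and 3 adjusted over the list alone, median -0.35, camera adjusted p = 0.0399, and adjusted p = 0.426 with an estimated correlation and 0.0614 with the replicate block), among them the lactate transporter SLC16A3 (-1.30) and the hexokinase HK3 (-1.03). Oxidative phosphorylation genes were lower in 13 of 30 (13 adjusted over the list alone, camera adjusted p = 0.00884, and adjusted p = 0.663 with an estimated correlation), such as SDHA (-0.65) and UQCRC1 (-0.83). Lysosome genes were lower in 16 and higher in 3 of 33 (the same counts adjusted over the list alone, camera adjusted p = 0.00221, and adjusted p = 0.426 with an estimated correlation). Of these, TFEB, a master regulator of lysosome genes, fell by 1.40 and the protease gene CTSZ by 2.70.

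Stress, matrix and cell cycle lists leaned higher. Integrated stress and ER stress genes rose in 11 and fell in 2 of 19 (11 and 2 adjusted over the list alone, camera adjusted p = 0.0202, and adjusted p = 0.181 with an estimated correlation, 0.0648 without Early CTL 2 and 0.0704 without Late CTL 3), with the asparagine synthetase gene ASNS at 1.56 and XBP1 at 0.78. Coagulation, matrix and protease genes rose in 11 and fell in 2 of 21 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00447, and adjusted p = 0.051 with an estimated correlation), led by the metalloproteinases MMP12 (2.69), MMP10 (2.00) and MMP1 (1.44). Cell cycle genes rose in 11 and fell in 1 of 21 (11 and 1 adjusted over the list alone, camera adjusted p = 0.0198, and adjusted p = 0.0735 with an estimated correlation), with TPX2 at 2.19, CCNB1 at 1.33 and PCNA at 0.76. Their summed level was low, 131 ± 3.85 CPM early and 171 ± 8.49 CPM late over 29 genes. Tested genes with a mean CPM of 1 to 10 also leaned higher late (925 higher and 535 lower). The list test does not adjust for abundance, so it cannot part the cell cycle list from that rise.

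The largest rises were mostly in low-abundance genes, and 6 of the 8 had an early mean CPM under 1. CCDC168 went from 2 counts to 99, a ratio of 75.3 per count sequenced (95% exact interval 20.3 to 630.0). RAPGEF5 (19.4-fold), PCDHAC2 (15.5-fold, in the protocadherin cluster, whose genes share exons), MEIS2 (14.4-fold), FLG2 (12.7-fold) and CCL8 (12.7-fold) also started under 1 CPM. TSLP, a cytokine known from epithelia, rose 14.0-fold from 2.68 ± 0.74 to 34.1 ± 1.68 CPM, and FABP4, a fatty acid carrier, 9.69-fold from 1.28 ± 0.60 to 11.2 ± 2.14 CPM. Largest among the falls were CCR2, the receptor for CCL2 (12.9-fold, from 6.52 ± 2.04 CPM), ACVR1B (8.36-fold), the lipid droplet gene HILPDA (7.8-fold), ALDH3A1 (6.73-fold), CTSZ (6.49-fold), CXCL10, LRRC25 (5.98-fold) and S100A9. The stress and redox genes FOS (613 ± 17.1 to 143 ± 12.8 CPM) and TXNIP (443 ± 24.4 to 81.4 ± 2.73 CPM) fell as well. Names of TSLP, FLG2, CCR2, HILPDA and IL1B rest on the authors' deposited table or a gene description. Related genes moved less firmly: TET3, a paralog of TET2, did not pass (0.31, adjusted p = 0.122), and of DNMT3A and ASXL1, often mutated in clonal hematopoiesis, DNMT3A rose by 1.64 (adjusted p = 0.0122) and ASXL1 fell by 0.34 (adjusted p = 0.0382, edgeR quasi-likelihood test). DNMT3A was low, at 0.91 to 1.01 CPM in early and 1.02, 3.27 and 3.86 CPM in late unstimulated libraries. Low-abundance genes as a class were higher late, and the rise of DNMT3A cannot be told apart from theirs. DNMT3A lost its call without Late CTL 2 or Late CTL 3 (adjusted p = 0.0508 and 0.0781), and ASXL1 lost its call in 8 alternatives (adjusted p from 0.0504 to 0.202), among them without Early CTL 2 or 3 or Late CTL 1 or 2.

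**Figure D2:**
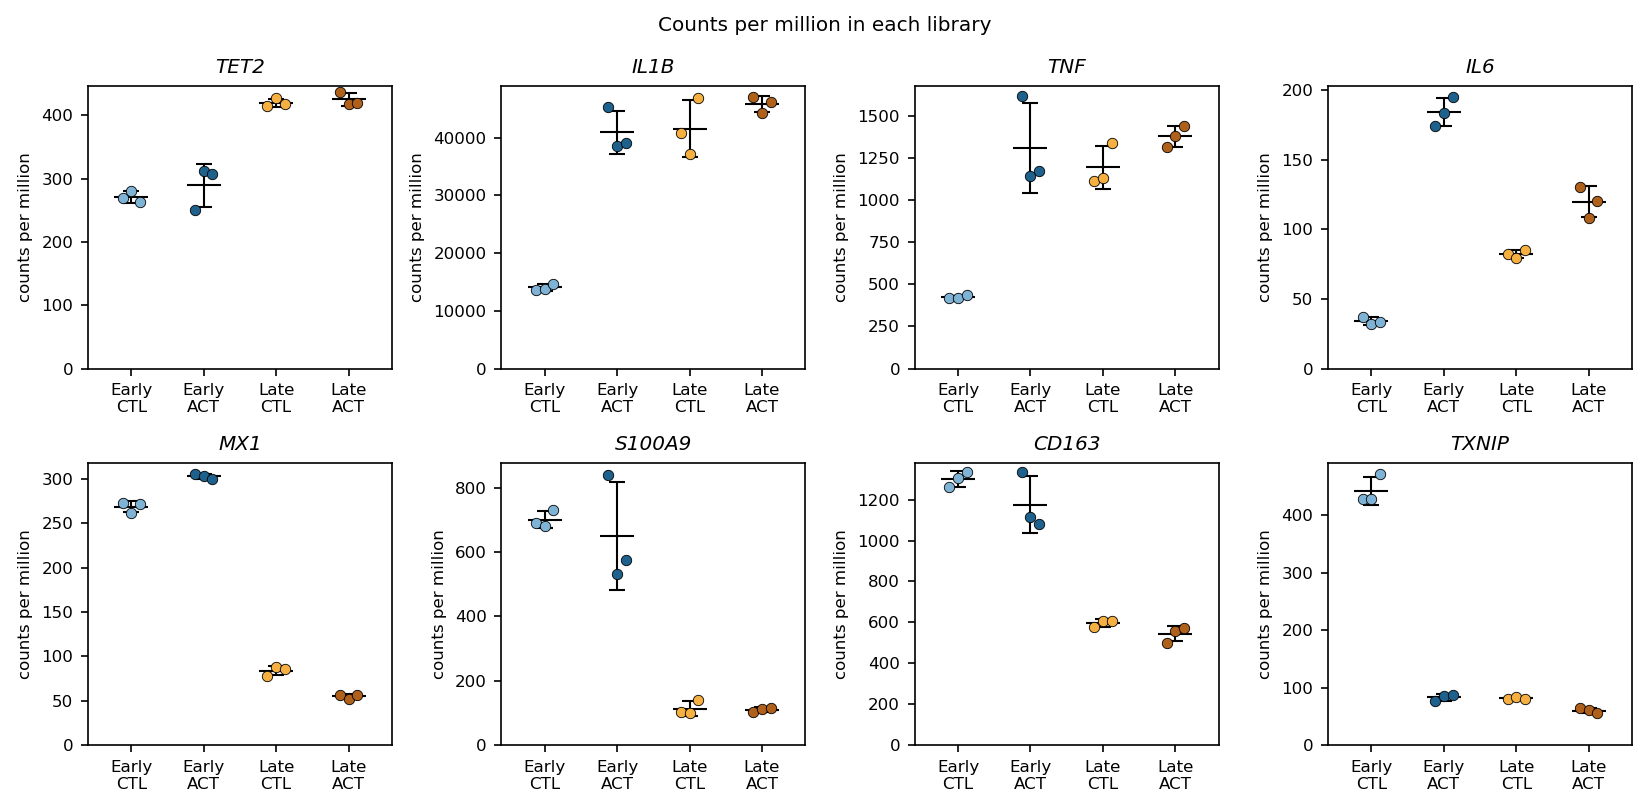
CPM of 8 genes in the 4 groups, with a point per library and the mean ± SD (n = 3) in black. IL1B and TNF are high in 3 of the 4 groups (means of 40960 to 45840 and of 1197 to 1381 CPM) and low in early unstimulated cells, while MX1 and S100A9 are low in both late groups.

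Stimulated macrophages at 19 months had far lower levels of interferon-stimulated genes than at 4.5 months, while IL1B and TNF did not differ detectably. OAS2 was 9.18-fold lower, at 193 ± 15.7 CPM early and 23.2 ± 5.91 CPM late (SD, n = 3 each), and MX1 6.09-fold lower (303 ± 3.02 to 55.2 ± 2.41 CPM). IL1B had a log2 fold change of 0.01 ± 0.11 SE (adjusted p = 0.949) and TNF of -0.08 ± 0.13 (adjusted p = 0.652, edgeR quasi-likelihood test). IL6, another LPS-induced cytokine, was 1.71-fold lower late, from 184 ± 10.2 to 119.8 ± 11.0 CPM, and NLRP3 2.0-fold lower, from 702 ± 62.5 to 389.9 ± 10.2 CPM.

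The edgeR quasi-likelihood test called 4589 genes after Benjamini-Hochberg adjustment, 2263 higher and 2326 lower late. Below a mean CPM of 1, where the filter by group selects in the same way, 376 of 630 tested genes were higher and 4 lower, and above 100 CPM 220 were higher and 665 lower. The share higher was 49.3%, against 61% with upper-quartile factors (median of all genes 0.15 in place of 0.05) and 58.6% with DESeq2 on its own set of 17167 genes. In the authors' deposited table for stimulated cells 3985 genes are listed, 2177 of them higher.

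Of the 28 tested interferon-stimulated genes 25 fell (25 adjusted over the list alone) and none rose, with a median of -1.88 (camera adjusted p = 7.21e-18). OAS3 (-2.51), IFIT5 (-2.81) and MX2 (-2.08), all antiviral effectors, were among them, and IFIT2 (-2.43), named only by a description in the authors' deposited table, fell too but is not in the tested list. Interferon-gamma response genes fell in 15 of 19 (16 adjusted over the list alone, median -0.73, camera adjusted p = 1.83e-06), including PSMB8 (-1.62), PSMB9 (-1.71), PARP14 (-1.05) and CXCL10, which went from 16.5 ± 3.49 to 3.73 ± 1.26 CPM. Cytokines and chemokines split into 4 higher and 4 lower of 15 (the same adjusted over the list alone, median 0.01, camera adjusted p = 0.82), with CCL2 at 0.91, CCL8 at 1.43 and LIF at 0.65. With an estimated correlation the camera adjusted p was 2e-04 for the interferon-stimulated list and 0.00577 for the interferon-gamma list.

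CD14 monocyte markers fell in 8 of 9 members (8 adjusted over the list alone, camera adjusted p = 2.51e-06, and adjusted p = 0.00973 with an estimated correlation). S100A8 was at -2.24, S100A9 at -2.71 and CD163 at -1.27 ± 0.11 (adjusted p = 5.4e-09, edgeR quasi-likelihood test), with CD14 itself at -0.82. Cell cycle genes rose in 11 of 21 (11 adjusted over the list alone, camera adjusted p = 0.00354, and adjusted p = 0.0494 with an estimated correlation), including NUSAP1 and TPX2 (2.26), which act on the mitotic spindle. The summed level of the list was low, 130.5 ± 3.21 CPM early and 186.9 ± 9.23 CPM late over 29 genes. Tested genes with a mean CPM of 1 to 10 also leaned higher late (917 higher and 378 lower). The list test does not adjust for abundance, so it cannot part the cell cycle list from that rise.

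The remaining 7 lists that passed with the preset correlation lost the call with an estimated one. The NF-kB pathway and feedback list had 13 lower and 2 higher of 25 (14 and 2 adjusted over the list alone, camera adjusted p = 0.000249, and adjusted p = 0.117 with an estimated correlation), with the NF-kB subunit RELB at -1.07 and the inhibitors TNIP1 and TNIP2 at -0.93 and -1.36. Inflammasome genes were lower in 7 of 17 (7 adjusted over the list alone, camera adjusted p = 0.0157, and adjusted p = 0.0998 with an estimated correlation), among them the pore-forming GSDMD (-1.27) and NLRP12 (-1.11). Immediate-early and heat shock genes were lower in 10 and higher in 1 of 19 (the same adjusted over the list alone, camera adjusted p = 0.00313, and adjusted p = 0.123 with an estimated correlation), with FOS at -2.17, JUNB at -0.88 and the chaperone HSPH1 at 1.31.

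Glycolysis and hypoxia genes were lower in 15 and higher in 1 of 25 (15 and 2 adjusted over the list alone, camera adjusted p = 0.000393, and adjusted p = 0.123 with an estimated correlation), with GAPDH at -1.08, PGK1 at -1.02 and HK3 at -1.24. Of the oxidative phosphorylation genes 13 of 30 were lower (13 adjusted over the list alone, camera adjusted p = 0.000393, and adjusted p = 0.45 with an estimated correlation), as for the complex I gene NDUFS7 (-1.34). Of the lysosome genes 21 were lower and 2 higher of 33 (22 and 2 adjusted over the list alone, camera adjusted p = 5.1e-05, and adjusted p = 0.253 with an estimated correlation), with GRN at -0.77, TPP1 at -0.76 and CTSZ at -1.74. Cytosolic ribosomal protein genes were lower in 13 and higher in 1 of 56 (3 and 1 adjusted over the list alone, median -0.21, camera adjusted p = 0.0111, and adjusted p = 0.723 with an estimated correlation and 0.363 without Early ACT 1).

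AKR1B10, an aldo-keto reductase, had the largest rise (23.8-fold, 0.351 ± 0.318 to 8.99 ± 3.55 CPM), followed by PCDHAC2 (23.6-fold), FBN1 (9.26-fold), ANK3 (8.08-fold), RNF152 (6.37-fold), MLC1 (6.08-fold), CTTNBP2 (5.96-fold) and RHOT1 (5.91-fold). Of these, 5 had an early mean CPM under 1. The largest falls, besides OAS2, MX1, OAS3, IFIT2 and IFIT5, were in FFAR2 (7.67-fold), a receptor for short-chain fatty acids, S100A9 (6.55-fold, 649 ± 168 to 110.0 ± 7.46 CPM) and HILPDA (6.49-fold).

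At 4.5 months LPS and interferon-gamma raised inflammatory cytokine genes. IL6 rose 6.57-fold, from 34.1 ± 2.88 to 184 ± 10.2 CPM (SD, n = 3 each), TNF 3.75-fold, from 425 ± 8.43 to 1313 ± 267 CPM, and IL1B 3.54-fold, from 14050 ± 605 to 40960 ± 3749 CPM. NLRP3 rose 3.26-fold, from 261 ± 4.53 to 702 ± 62.5 CPM. TXNIP, which binds thioredoxin and restrains glucose uptake, fell 4.4-fold, from 443 ± 24.4 to 83.0 ± 5.48 CPM. CD14 (0.24 ± 0.13 SE, adjusted p = 0.285) and CD163 (0.13 ± 0.11, adjusted p = 0.526, edgeR quasi-likelihood test) did not pass.

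By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 855 genes changed, 541 higher and 314 lower. The count moved with single libraries and with the tool: it was 485, 464 and 483 without Early CTL 1, 2 and 3, 1554 without Early ACT 1, and 503 when only these groups were fitted. With limma-voom it was 2379, 1221 higher and 1158 lower. Above a mean CPM of 100, 246 genes were higher and 34 lower.

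All 15 tested cytokine and chemokine genes rose (15 adjusted over the list alone). Their median was 1.76 (camera adjusted p = 3.66e-34, and adjusted p = 2.48e-05 with an estimated correlation). Besides IL6 and TNF, they included CSF3 (5.24-fold, 189 ± 6.71 to 816 ± 147 CPM) and the macrophage inflammatory protein gene CCL4L1 (4.59-fold). Outside the tested list, CCL3 rose 4.2-fold and CXCL2 3.99-fold (2039 ± 66 to 6724 ± 1814 CPM), and like CCL4L1 they have close paralogs that can share reads. IL12A, a subunit of the cytokine that primes T helper cells, rose 7.62-fold from 0.879 ± 0.487 to 5.70 ± 1.60 CPM. NF-kB pathway and feedback genes rose in 11 of 25 (16 adjusted over the list alone, camera adjusted p = 3.7e-09), with the inhibitors TNFAIP3 at 0.91 and NFKBIA at 0.80, TNFAIP6 at 1.16 and TRAF1 at 0.96.

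Interferon-stimulated genes rose in 11 of 28 tested members (16 adjusted over the list alone, median 0.47, camera adjusted p = 9.7e-09), with OASL at 1.19, DHX58 and ISG20 at 1.07 each and IFIT3 at 0.86. The helicase gene DDX60 rose 4.23-fold. Genes of the interferon-gamma response did not move as a list, with 2 higher and 1 lower of 19 (the same adjusted over the list alone, median -0.02, camera adjusted p = 0.9). These 19 are part of a list of 32, and GBP1, GBP2, GBP4 and GBP5, which had no usable name, are not among them. IDO1, which degrades tryptophan, rose by 0.55 ± 0.12 SE (adjusted p = 0.00282) and the Fc receptor gene FCGR1A by 0.47 (adjusted p = 0.0107), while GBP7 fell by 1.09 (adjusted p = 0.0453, edgeR quasi-likelihood test). FCGR1A lost the call without Early CTL 1 or 2 (adjusted p = 0.0948 and 0.0617), and GBP7 lost it without Early CTL 1, 2 or 3 or Early ACT 2 or 3 (adjusted p from 0.0581 to 0.133). CD274, the checkpoint ligand, did not pass (-0.40, adjusted p = 0.107). CXCL10 was at 26.96 to 34.75 CPM in early unstimulated and 12.6 to 19.33 CPM in early stimulated libraries.

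Integrated stress and ER stress genes rose in 12 of 19 (12 adjusted over the list alone, camera adjusted p = 2.49e-09), with ASNS at 1.52, CHAC1 at 1.33, SHMT2 at 1.16 and SESN2 at 1.07. Coagulation, matrix and protease genes rose in 9 of 21 (11 adjusted over the list alone, camera adjusted p = 1.71e-08). PLAUR, the urokinase receptor, was 3.25-fold higher and SERPINB2, the urokinase inhibitor, 2.07-fold (13990 ± 124 to 23890 ± 1574 CPM), with MMP10 at 1.47 and MMP1 at 1.18.

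Calls that did not hold with an estimated correlation were those of 3 lists. Cytosolic ribosomal protein genes had 0 of 56 called, by the edgeR quasi-likelihood test, and a median of 0.23 (camera adjusted p = 7.92e-06, and adjusted p = 0.709 with an estimated correlation and 0.432 without Early ACT 1). Neutrophil markers rose in 2 of 9 (4 adjusted over the list alone, camera adjusted p = 0.00576, and adjusted p = 0.278 with an estimated correlation and 0.121 without Early ACT 1), the members being LCN2 (1.01) and MGAM (1.22). LCN2 lost its call without Early CTL 1 (adjusted p = 0.089), and MGAM without Early CTL 1, 2 or 3 or Early ACT 3 (adjusted p from 0.0735 to 0.182). The inflammasome list had 6 higher and 2 lower of 17 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0422, and adjusted p = 0.122 with an estimated correlation, or 0.0508 to 0.0909 without Early CTL 2 or 3 or Early ACT 2 or 3), with the decoy receptor IL1R2 at 1.02 and NLRP12 at -0.96. Single genes of other lists rose too, such as the glucose transporter SLC2A1 (1.03) and the cyclin CCNB1 (3.89-fold).

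Falls were largest in CSPG4 (9.57-fold, 6.41 ± 1.12 to 0.438 ± 0.466 CPM), the RNA-sensing receptor TLR8 (4.79-fold), TIFAB (4.53-fold), TXNIP, TRIM23 (3.75-fold), the peptidase ANPEP (3.69-fold), PPP1R9B (3.58-fold) and CCR2 (3.44-fold). All of these except TXNIP started under 10 CPM. PPP1R9B lost the call without Early CTL 1 or Early ACT 3 (adjusted p = 0.159 and 0.0698), and CCR2 without Early CTL 1, Early CTL 3 or Early ACT 3 (adjusted p = 0.111, 0.0554 and 0.05).

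At 19 months stimulation changed no gene past the threshold by the edgeR quasi-likelihood test with the main settings. IL6 went from 82.4 ± 2.86 to 119.8 ± 11.0 CPM (SD, n = 3 each), a log2 fold change of 0.57 ± 0.12 SE (adjusted p = 0.111), and MX1 from 83.9 ± 5.26 to 55.2 ± 2.41 CPM (-0.57 ± 0.11, adjusted p = 0.0691, edgeR quasi-likelihood test). IL1B (0.17 ± 0.11), TNF (0.24 ± 0.13), NLRP3 (0.24 ± 0.11), CD14 (-0.05 ± 0.13) and CD163 (-0.10 ± 0.11) each had an adjusted p of 0.9985 by the edgeR quasi-likelihood test. OASL, an interferon-stimulated gene, was at 0.66 (adjusted p = 0.266) and FOS, an immediate-early gene, was at -0.47 with an adjusted p of 0.342. Some genes did not pass although their late libraries did not overlap. IL12A was at 3.58 to 5.17 CPM unstimulated and 10.84 to 16.37 CPM stimulated, and DDX60 at 11.41 to 15.1 and 30.31 to 32.36 CPM. TXNIP was lower, at 79.53 to 84.49 and 55.23 to 63.95 CPM. The lack of calls therefore does not show that late cells did not respond.

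The edgeR quasi-likelihood test called 0 of 11826 genes, with 527 at an unadjusted p under 0.05, while DESeq2 called 15 and limma-voom 20. Cytokines and chemokines had a median of 0.24 with 0 of 15 called by the edgeR quasi-likelihood test (2 higher adjusted over the list alone, camera adjusted p = 0.00179, and adjusted p = 0.0727 with an estimated correlation). Lysosome genes (median -0.10, camera adjusted p = 0.014, and adjusted p = 0.65 with an estimated correlation) and immediate-early and heat shock genes (median -0.11, camera adjusted p = 0.0049, and adjusted p = 0.195 with an estimated correlation) leaned lower. Without Late ACT 1 these became 0.0574 and 0.112, and without Late CTL 3 the lysosome list had an adjusted p of 0.232. Adjusted over the list alone, 0 lysosome genes and 1 immediate-early gene, lower, passed the edgeR quasi-likelihood test. Interferon-stimulated genes had 3 higher and 4 lower of 28 adjusted over the list alone (median -0.22, camera adjusted p = 0.084).

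**Figure D3:**
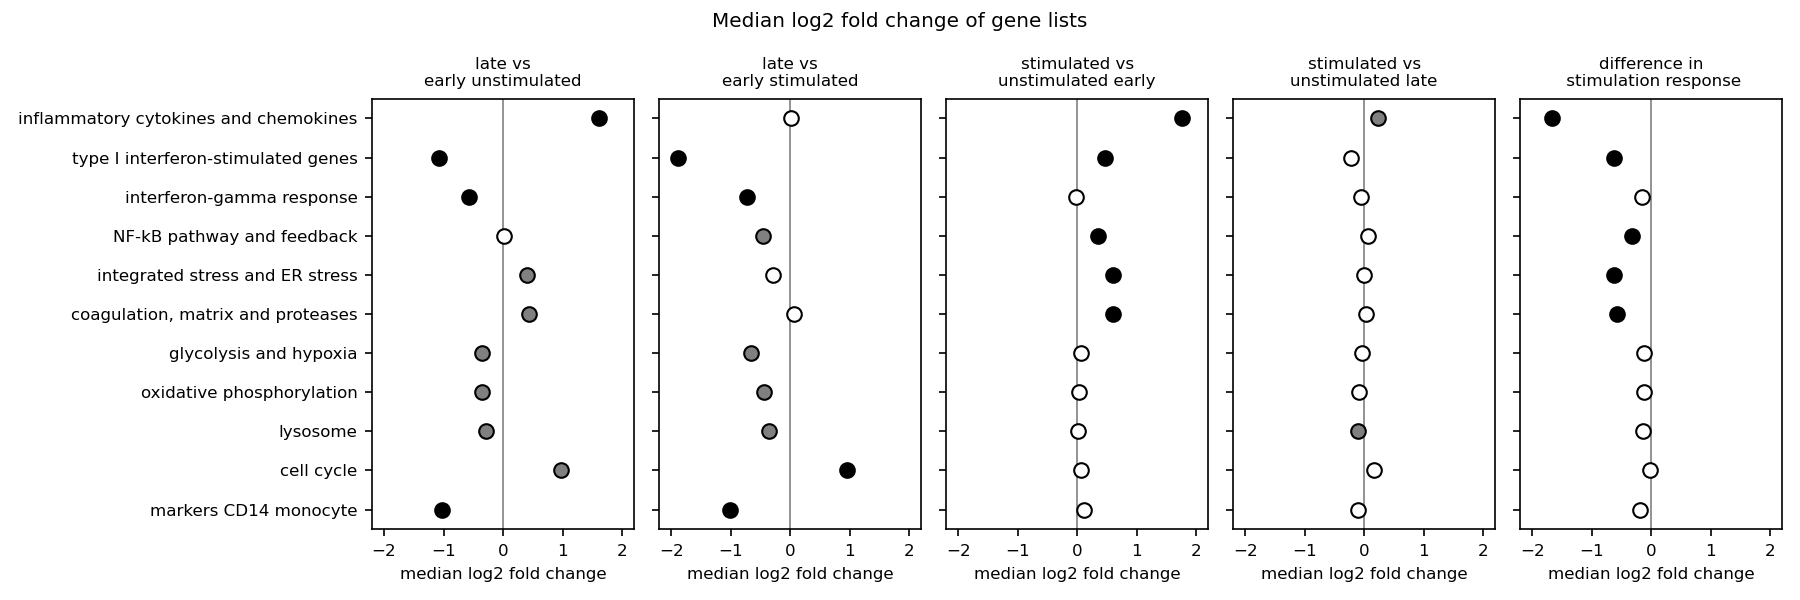
Median log2 fold change of the tested members of 11 gene lists (vertical axis: list, horizontal axis: log2 fold change) in the 5 comparisons. Black points have an adjusted p under 0.05 also with an estimated correlation, grey points only with the preset correlation, white points with neither, and the cytokine list is at 1.62 for late against early unstimulated, 1.76 for early and 0.24 for late stimulation.

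The response to stimulation was smaller at 19 than at 4.5 months for inflammatory genes. The log2 change of IL6 was smaller by 2.14 ± 0.17 SE late (-2.14, adjusted p = 9.17e-09), that of IL1B by 1.65 ± 0.15 (-1.65, adjusted p = 9.72e-08) and that of TNF by 1.67 ± 0.18 (-1.67, adjusted p = 1.13e-06, edgeR quasi-likelihood test). For IL1B and TNF, late unstimulated cells were already near the level of stimulated cells, at 41580 ± 4882 and 1197 ± 128 CPM (SD, n = 3 each). IL6 reached 184 ± 10.2 CPM in early and 119.8 ± 11.0 CPM in late stimulated cells.

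A smaller or more negative late response was called for 145 genes and a larger or less negative one for 22, 167 in all, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 100 and 95 without Early CTL 1 and 2, 546 without Early ACT 1, and 106 and 104 without Late ACT 1 and 3. DESeq2 gave 313 genes (43 higher and 270 lower) and limma-voom 605 (160 higher and 445 lower). All 15 cytokine and chemokine genes had a smaller response (15 adjusted over the list alone, median -1.66, camera adjusted p = 1.39e-36), as had 6 of 28 interferon-stimulated genes (19 adjusted over the list alone, median -0.63, camera adjusted p = 4.8e-11). MX1 rose by 0.45 ± 0.11 on early stimulation and not on late stimulation (-0.57 ± 0.11), a difference of -1.02 ± 0.16 (adjusted p = 0.000196, edgeR quasi-likelihood test). TXNIP differed the other way (1.73 ± 0.16, adjusted p = 9.72e-08, edgeR quasi-likelihood test), from a level of 81.4 ± 2.73 CPM in late unstimulated and 443 ± 24.4 CPM in early unstimulated cells.

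Differences between the times were largely shared by stimulated and unstimulated cells. The list of cytokines and chemokines was an exception, with a median of 1.62 in unstimulated and 0.01 in stimulated cells. Across the 11826 genes the late over early log2 fold changes of unstimulated and stimulated cells had a Pearson r of 0.836 (Spearman 0.787), with 3312 genes called in both and 3285 of these in the same direction, 1583 higher and 1702 lower. Lists of these sizes would share 472.8 higher and 460.6 lower genes if independent. The stimulation responses of the 2 times had an r of 0.098 (Spearman 0.144), or 0.295 among genes with a mean CPM over 10. Genes are not independent replicates, so these correlations carry no p.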

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

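All tests of explanations and all splits of the libraries in this part were chosen only after the results were seen, while the interaction test and its gene lists were not.

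The response to LPS and interferon-gamma differed between 4.5 and 19 months by a test of the difference itself, in which 167 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. A negative difference means a smaller or more negative change on late stimulation. Cytokines and chemokines had a median difference of -1.66, with all 15 tested genes called. IL6 (-2.14), TNF (-1.67), CSF3 (-2.13), CCL4L1 (-1.82), CXCL1 (-1.66), CCL8 (-2.23) and IL12B (-1.95) were among them. Outside the tested list, IL1B (-1.65), CCL3 (-1.83), CXCL2 (-1.80) and the inflammasome sensor NLRP3 (-1.46) were called too. Members of the NF-kB pathway and feedback list followed, with TNFAIP3 at -0.92, TNFAIP6 at -1.03, TRAF1 at -0.89 and NFKBIA at -0.79. That list had 4 of 25 called (7 adjusted over the list alone, median -0.32, camera adjusted p = 1.46e-06).

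Interferon-stimulated genes had a median difference of -0.63, with MX1 at -1.02, OAS2 at -0.98, MX2 at -0.73 and DHX58 at -0.74. Integrated stress genes had 7 of 19 called (12 adjusted over the list alone, median -0.62, camera adjusted p = 1.41e-09), with ASNS at -1.31, CHAC1 at -1.20, SHMT2 at -1.09 and SESN2 at -0.97. Coagulation, matrix and protease genes had 6 of 21 called (11 adjusted over the list alone, median -0.57, camera adjusted p = 5.33e-09), with PLAUR at -1.67, MMP10 at -1.31, MMP1 at -1.02 and SERPINB2 at -0.99. Immediate-early and heat shock genes (median -0.17, camera adjusted p = 0.00668, and adjusted p = 0.192 with an estimated correlation), with FOSL1 at -0.74, had 1 of 19 called (4 adjusted over the list alone). Cytosolic ribosomal protein genes had a median of -0.18 (camera adjusted p = 0.00954, and adjusted p = 0.782 with an estimated correlation), with 0 of 56 called by the edgeR quasi-likelihood test. The immediate-early call was lost without Late ACT 1 (adjusted p = 0.0507) and the ribosomal call without Early ACT 1, Late CTL 3 or Late ACT 3 (adjusted p = 0.838, 0.484 and 0.0544).

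Positive differences, mostly falls on early stimulation that were smaller or absent late, were found for CSPG4 (2.88), ALDH3A1 (2.57), ASB7 (2.08), ACADSB (1.98), TXNIP (1.73), ARID4A (1.48), LRRC25 (1.43) and DSTYK (1.41). CCDC168 was at -3.78, from a handful of early counts. Members of lists that did not pass here or were too small to test were called as well: IL1R2 (-0.94), SLC2A1 (-1.03), VEGFA (-0.55), PLIN2 (-0.85), TREM2 (-0.67), CCNB1 (-1.40) and TREML1 (-1.21). Of the 40 named genes called in this comparison, 28 were called in every alternative run. With single libraries left out, ACADSB, ALDH3A1, ARID4A, ASB7, CCDC168, CCL8, DHX58, DSTYK, IL12B, MX2 and TREM2 lost the call without at least 3 of the 12, with adjusted p up to 0.184 (ASB7), and OAS2 lost it without Late ACT 2 (adjusted p = 0.0541).

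Of 100 splits drawn from the 200 that regroup the libraries within each time, 9 gave at least 167 genes, the real one included, and the highest gave 400. This share does not exclude chance. All 9 kept the early stimulated and unstimulated libraries in their groups, which keeps the early response in the difference, and the real split gave the fewest genes of the 9, while no drawn split that broke the early groups gave as many.

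The first pattern weighed is the high level of inflammatory genes in late unstimulated cells, where IL1B and TNF were near their levels in stimulated cells. Scaling of the libraries is argued against by the list's median log2 fold change, which was 1.66 at its lowest under RLE or upper-quartile factors. The background that raised low-abundance genes is argued against by size, for the list as a sum. The listed genes gained 2.58 times the CPM that all low-abundance genes gained together (8599 against 3326 CPM). Such a sum is set by members with many counts. The background stays open for low members such as CCL8 (0.41 to 0.64 CPM in early and 5.55 to 7.67 CPM in late unstimulated libraries). Activation of the cells by handling on the late day remains open: of 573 genes called both for late over early in unstimulated cells and for early stimulation 518 had the same sign, but the interferon-stimulated list went opposite ways (-1.08 and 0.47), and the comparisons share the 3 early unstimulated libraries. Of the 518 genes 325 were higher and 193 lower, where independent lists of these sizes would hold 113 and 62.2 in common. In 5 simulations of the shared libraries without any effect 0 genes were called in both. There the mean covariance was 0.085 against 0.373 observed, the mean r 0.455 against 0.483, and the Spearman correlation 0.415 to 0.437 against 0.396. Shared libraries without effects thus gave no such overlap. These simulations hold no time or stimulation effect, so they cannot say how far shared libraries raise the overlap or r of real effects. Handling on that day may explain the pattern, and it cannot be told apart from the time since transplant or a change of the TET2-mutant clones, which are untested.

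The second pattern is the absence of a rise in the tested interferon-gamma response genes on stimulation. Of the 32 listed genes 19 were tested, without GBP1, GBP2, GBP4 and GBP5. Genes already at their highest level without stimulation remain possible: the list started lower in late cells and had a median log2 fold change of -0.05 there. Late cells had 0 genes called by the edgeR quasi-likelihood test with the main settings (527 at an unadjusted p under 0.05). Alternatives called few genes (5 with no low-count filter, 10 with only the compared groups, DESeq2 15, limma-voom 20). With so little late response the median does not decide. No interferon-gamma signal in the stimulated wells may also explain it, and the 2 tested members of the list that rose on early stimulation restate the pattern and do not test that. The protocol names interferon-gamma and the treatment field of the labels does not, so these explanations cannot be told apart here. No biological explanation was tested for this pattern.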

How the results depend on the processing

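No gene or list called in both the main test and an alternative changed direction. Neither did any called gene among the named ones, or any correlation. Other genes and lists that lost their call were not checked for direction. Medians near 0 of lists without a call did change sign. The balance of higher and lower genes in stimulated cells turned from 2263 and 2326 to 2882 and 1845 with upper-quartile factors. It also turned with RLE factors (2448 and 2178), DESeq2 (3029 and 2138), limma-voom (2646 and 2572), no low-count filter (3306 and 2458), CPM above 1 in at least 3 libraries (2525 and 2429) and an absolute log2 fold change over 1 (1230 and 668). In unstimulated cells it turned from 2471 and 2342 to 1622 and 1798 at a mean CPM of at least 5. It also turned there with only the compared groups (2309 and 2387) and, barely, at an adjusted p of 0.01 (1664 and 1666). The filter at a mean CPM of 5 and the list members named by the authors' tables were chosen after the data were seen. With an absolute log2 fold change over 1 the counts of genes were 2259 and 1898 for late against early in unstimulated and stimulated cells, 239 for early stimulation and 93 for the interaction. At an adjusted p of 0.01 they were 3007 for stimulated cells, 426 for early stimulation and 87 for the interaction. These follow from the stricter thresholds. Early stimulation gave 2379 genes with limma-voom, 503 with only the compared groups fitted, and 464 to 1554 with a library left out (485, 464 and 483 without Early CTL 1, 2 and 3, 1554 without Early ACT 1). Late stimulation gave 2 with upper-quartile factors, 15 with DESeq2, 20 with limma-voom, 5 with no low-count filter, 10 with only the compared groups, and 0 to 2 with a library left out (2 without Late CTL 1), in place of 0 by the edgeR quasi-likelihood test (527 at an unadjusted p under 0.05). The interaction gave 313 with DESeq2, 605 with limma-voom and 95 to 546 with a library left out (95 and 100 without Early CTL 2 and 1, 104 and 106 without Late ACT 3 and 1, 546 without Early ACT 1), and it could not be fitted with only a pair of groups. Late against early ran from 4254 to 4582 and from 3689 to 4652 with a library left out. The count of lists fell with an estimated correlation to 4, 4, 5 and 0 for the first 4 comparisons (from 10, 11, 8 and 3), and with fry it was 18 and 19 for late against early and 1 for late stimulation. With a library left out it ran from 1 (without Late ACT 1) to 4 for late stimulation and from 6 to 11 (without Early ACT 3) for the interaction, against 7. The correlation of the stimulation responses rose from 0.098 to 0.295 for genes with a mean CPM over 10 and ran from 0.075 to 0.105 with a library left out, and that of the time differences ran from 0.808 (without Early ACT 2) to 0.829, with 0.813 without Early ACT 3, against 0.836. Of 5099 values for named genes under alternatives, 4912 stayed on their side of the threshold, 136 fell below it and 51 rose past it, and of 510 for lists 466 stayed and 44 fell below it. With a replicate block, as if equal numbers paired the samples, 4596, 4354, 727, 0 and 114 genes were called, the 0 by the edgeR quasi-likelihood test. Of 18 same-numbered pairs 0 had an r over 0.1 (lowest -0.09, highest 0.1), which gave no sign that the numbers pair the samples. A correlation over all tested genes carries the noise of low counts, so it cannot exclude pairing. Except for thresholds and sample numbers, the cause was not tested. Depth limits the genes with a mean CPM under 1, of which 630 of 15151 were tested. Of 2-fold differences of the interaction, 38% were recovered in simulated data, among genes with a mean CPM over 1.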

Other observations

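All tests of explanations and all splits in this part were chosen only after the results were seen, while the gene lists were not.

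Some antioxidant genes controlled by NRF2 were higher late. The glutathione and cystine genes GCLM and SLC7A11, the sulfiredoxin SRXN1 and the quinone reductase NQO1 were among them, at 1.13, 1.24, 1.10 and 1.70 in unstimulated and 1.40, 1.08, 1.00 and 1.79 in stimulated cells (edgeR quasi-likelihood test). The list itself did not pass, with 5 higher and 5 lower of 16 in unstimulated cells (6 and 5 adjusted over the list alone, camera adjusted p = 0.72), and 5 and 5 in stimulated cells (camera adjusted p = 0.504). Heme oxygenase HMOX1, chosen after its values were seen, went the other way (-1.31 in unstimulated cells, adjusted p = 5.45e-07, edgeR quasi-likelihood test).

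Lipid genes also went both ways. APOE, a carrier of cholesterol, rose 5.29-fold late in unstimulated cells (3.73 ± 1.32 to 18.9 ± 7.72 CPM, SD, n = 3), as did the lipid droplet gene PLIN2 (0.81), whereas the lipid synthesis regulator SREBF1 fell by 1.09. The list of LXR targets and lipid handling had 6 higher and 6 lower of 16 (7 and 8 adjusted over the list alone, camera adjusted p = 0.886). Its median was -0.05 but 0.08 with upper-quartile factors, and its mean was 0.17. Cholesterol synthesis genes had 1 higher and 3 lower of 15 (camera adjusted p = 0.733). In stimulated cells TREM2, a lipid-sensing receptor, was at -1.07.

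Other lists did not pass for late against early in unstimulated cells. Among 18 genes of clonal hematopoiesis and DNA methylation 6 were higher and 6 lower (6 and 7 adjusted over the list alone, camera adjusted p = 0.948), including UHRF1 (1.42) and CBL. MHC class II genes had 1 higher and 3 lower of 10 (camera adjusted p = 0.473), NF-kB genes 5 and 6 of 25 (camera adjusted p = 0.733), genes that sense LPS and interferon-gamma 3 and 7 of 19 (camera adjusted p = 0.733), and alternative activation genes 4 and 6 of 17 (camera adjusted p = 0.81). The inflammasome list had 4 and 4 of 17 (camera adjusted p = 0.72), with a median of 0.09 and a mean of -0.26. Immediate-early and heat shock genes had 4 higher and 8 lower of 19 (camera adjusted p = 0.355).

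Marker genes of other blood cells were few in counts. Their summed CPM in early and late unstimulated libraries was 292 ± 13.6 and 332 ± 15.4 for T cells, 21.7 ± 1.00 and 22.0 ± 3.88 for B cells, 67.9 ± 1.30 and 59.1 ± 3.95 for NK cells, 182 ± 11.8 and 106 ± 16.7 for neutrophils, and 521 ± 26.5 and 392 ± 36 for platelets (SD, n = 3 each). The markers of CD14 monocytes summed to 12963 ± 225 and 6901 ± 283 CPM.

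The remaining pattern is the higher level of low-abundance genes in late libraries. Fewer molecules sampled in early libraries is argued against by the summed CPM of genes with a mean CPM under 1, which was 3.35 times as high late (2.75 times between the closest libraries), since sampling changes how many genes are seen and not their summed share. RNA from other blood cells is argued against by 0 of 9 marker lists being higher in every late than in every early library, with 2 lower. In unstimulated cells alone T cell markers were higher late (322.2 to 350.1 against 282.0 to 307.4 CPM). They were not in stimulated cells (307.3 to 326.6 late and 215.1 to 346.3 CPM early). Of 5 tested plasmacytoid dendritic cell markers 3 were called higher and 0 lower in unstimulated cells, while 0 were higher and 1 lower in stimulated cells. Background counts that do not depend on expression, such as from genomic DNA, may explain the pattern. Of 84 olfactory receptor genes, 10.5 times as many had a count at equal depth late (2.33 and 5.0 early, 37.7 and 39.3 late). Their summed CPM rose from 7.91 and 10.2 to 31.2 and 31.8 in unstimulated and stimulated libraries. That macrophages do not express these genes was assumed and not tested. Early CTL 1 held 50 of their counts in 2 genes, so real expression of some stays possible. A wider range of genes expressed at 19 months was not tested apart from such background. No label gives a library day, so the times cannot be told apart from any batch that went with them.

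For late against early, the splits of the 6 libraries number 10, so a share under 0.05 cannot be reached. Unstimulated cells gave 4813 genes in the real split (1 of 10 as large) and 0 at most in the others. Stimulated cells gave 4589 (1 of 10) with 0 at most in the others, and early stimulation 855 (1 of 10) with 0 at most in the others. Late stimulation gave 0 genes by the edgeR quasi-likelihood test (527 at an unadjusted p under 0.05, DESeq2 15, limma-voom 20), 10 of 10 splits gave as many, and the highest other gave 1.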
